A study of Mus musculus with 6 samples.

How the data were processed

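RNA from whole mammary glands of 3 wild-type and 3 Cav-3 knockout virgin females, all 4 months old and of the FVB/N background, was measured on single-channel Affymetrix mouse arrays. Total RNA was extracted with Trizol, reverse transcribed from an oligo-dT primer carrying a T7 promoter and copied into biotin-labelled cRNA, per the labels' protocols. Groups and replicate numbers come from the sample titles, and the labels do not state whether each gland came from a different mouse or whether replicate numbers pair the samples.

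The deposited values are on a log2 scale, 1 per probe set and array, and were made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays against each other and summarises the probes of a set into 1 log2 value. Its version and the software that ran it were not given in the sources used here. Quantile normalization forces the same distribution on each array, so a shift of most transcripts in one direction would be removed, and RMA compresses folds of dim probe sets. Array medians of 5.77 to 5.80 and a shared range were checked. No genome build was given, and no coordinates are used from the values.

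Of 45101 deposited probe sets, 64 control sets were left out of the tests and 45037 were tested, without a filter on dim sets. Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and were not named, and 9160 were not listed there and stay unnamed here. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6; 204 single-symbol sets had no match and kept the annotation's name. Each of 18193 genes is shown by the probe set with the highest mean over the 6 arrays, and genes whose sets passed in opposite directions are counted in the text. The RefSeq table also gave which genes neighbour Cav3.

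Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, 4 residual degrees of freedom), with the genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. All differences are knockout minus wild type on the log2 scale, with moderated standard errors. Figures were drawn with matplotlib 3.10.9.

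Before the data were examined, the design, the alternatives, 34 gene lists (19 pathways and 15 cell types) and the rule for naming genes were fixed. The rule names Cav3, then the 15 highest and 15 lowest log2 differences among genes past the threshold whose 3 knockout arrays all lie on one side of the 3 wild-type arrays, then 2 to 4 members of each list with the smallest p. Genes named for another reason are said to be so. The pathways were milk proteins and secretory differentiation, prolactin and STAT5 signalling, oestrogen and progesterone response, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and thermogenesis, caveolae, the dystrophin complex, endoplasmic reticulum folding, proliferation, interferon response, inflammation, extracellular matrix, TGF-beta targets, oxidative phosphorylation, glycolysis, immediate early genes, the circadian clock and tumour-suppressive regulators. The cell types were luminal and basal epithelium, white and brown adipocytes, skeletal muscle, vascular smooth muscle, endothelium, fibroblasts, macrophages, T cells, B cells, neutrophils and mast cells, erythroid cells, epidermis and Schwann cells. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 34 lists, and members were counted by p adjusted over all probe sets and again over the list alone. Lists share few genes: the oxidation and brown adipocyte lists share 7, the extracellular matrix and fibroblast lists 5 and the basal and vascular smooth muscle lists 4.

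Alternatives were quantile normalization again, cyclic loess, median centring, a filter on dim probe sets, another variance prior, array weights, each array left out in turn, the replicate number as a block, fewer probe sets, the mean of a gene's probe sets, other thresholds, camera with an estimated correlation and fry. After seeing the data the skeletal muscle list mean was added as a covariate for all results, since that list varied most between arrays among neighbouring tissues (SD of array means 1.15). The limma fit was tested on simulated data of 45037 probe sets in 3 against 3 arrays with 50 sets changed at each size: it recovered 8% at a log2 change of 0.5, 74% at 1, 92% at 2 and 100% at 3, with 6 false calls. In the real data 5547 probe sets passed, far more than were changed in the simulation. The adjusted threshold was therefore stricter in the simulation, and its recovery rates do not give the sensitivity of the real comparison. In the simulated test of lists, the 1 shifted list was called and 0 of 30 lists without its genes were, by camera. Simulated genes were independent, while the estimated correlation between real genes was 0.89 in the proliferation list. The simulation therefore does not show how often lists of correlated genes are called falsely.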

Results

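Messenger RNA was measured in whole mammary glands of 4-month-old virgin female mice of the FVB/N strain. The comparison was between 3 wild-type glands and 3 glands lacking caveolin-3 (Cav-3 knockout), and whether each came from a different mouse was not stated. Caveolin-3 is the caveola coat protein of muscle cells. Each gland was read on 1 single-channel oligonucleotide array, so there were 6 arrays in 2 groups. Array medians lay between 5.77 and 5.80 on the log2 scale. Correlations over all probe sets were 0.990 to 0.995 between arrays of the same genotype and 0.977 to 0.987 between genotypes. The first principal component of the 1000 most variable probe sets held 67.3% of their variance and placed the 3 wild-type arrays on one side and the 3 knockout arrays on the other. Array numbers, 3 per genotype, limit the precision. The stage of the oestrous cycle was not given in the sources used here.

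The gene disrupted in the knockout, Cav3 (Entrez 12391, represented by 1 probe set), had a log2 value of 4.85 ± 0.15 (SD, n = 3) in wild type and 4.77 ± 0.06 in knockout. The difference of −0.08 ± 0.10 (SE) was smaller than the spread between replicates (adjusted p = 0.679, and 0.6 by a two-sided exact permutation test, in which 10 splits allow no p below 0.1). Without wild-type 2 the difference was 0.0063. The mean of this probe set lay at percentile 36.5 of all probe sets, and whether its target lies in the removed part of the gene was not given in the sources used here. It therefore did not check the genotypes, which are as labelled. Fast and slow muscle genes, which mark the tissue where Cav3 is most active, varied between arrays: the mean of the skeletal muscle list was 7.13, 8.10 and 5.35 in wild-type 1 to 3 and 5.03, 6.0 and 6.47 in knockout 1 to 3.

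The comparison asked which transcripts of the resting gland change when caveolin-3 is missing, with milk production as the study's stated theme. Medians of the milk, epithelial and cell division lists were higher, while those of the fat, lipid synthesis, mitochondrial and lymphocyte lists were lower. Of 18193 genes, 1392 were higher and 1549 lower in knockout (16.2% of genes), and 429 of the higher and 238 of the lower ones changed at least 2-fold. Among 45037 probe sets, 2587 were higher and 2960 lower. The groups did not overlap for 6971 genes (38.3%, where chance gives 10%). The number of genes past the threshold was 1815, 1680 and 1470 without wild-type 1, 2 or 3, and 2485, 3181 and 1235 without knockout 1, 2 or 3. For 9 genes, probe sets passed in both directions.

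The 15 highest rises included 3 caseins and 2 connexins. The gap junction genes Gjb6 and Gjb2 rose by 4.84 ± 0.43 and 4.77 ± 0.27 on the log2 scale (SE), 28.7-fold and 27.2-fold. Olah, the thioesterase that releases medium-chain fatty acids in the lactating gland, rose by 4.77 ± 0.80 (adjusted p = 0.0103). Rspo1, a secreted enhancer of Wnt signalling, rose by 4.68 ± 0.42. Sftpd, a collectin of innate defence, rose by 4.66 ± 0.78. Bcl2l15, a member of the BCL2 family, rose by 4.64 ± 0.24. Chrdl2, an inhibitor of bone morphogenetic proteins, rose by 4.63 ± 0.76. Pigr, the receptor that carries antibody across epithelium into milk, rose by 4.49 ± 0.77. Car6, a secreted carbonic anhydrase, rose by 4.11 ± 0.27. The caseins Csn1s1, Csn2 and Csn1s2a rose by 3.79 ± 0.54, 3.65 ± 0.77 and 3.50 ± 0.82. The ion pump genes Atp6v1c2, Atp12a and Atp13a4 rose by 3.56 ± 0.37, 3.56 ± 0.39 and 3.49 ± 0.39. The wild-type mean of Atp12a, 2.99, lay within the range of 9 Y-linked probe sets on these female arrays (1.90 to 3.57), which stand for background, so its fold is understated.

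The 15 steepest falls included the brown fat genes Elovl3 and Ucp1. Ido1, which degrades tryptophan, fell by 3.63 ± 0.94 on the log2 scale (SE, adjusted p = 0.0443). Elovl3, a fatty acid elongase of brown fat, fell by 3.42 ± 0.20, and was 10.7-fold lower. Ucp1, the uncoupling protein of brown fat, fell by 3.36 ± 0.88 (adjusted p = 0.0453), from wild-type values of 10.35, 8.54 and 12.72 to 7.18 ± 0.33 (SD, n = 3). Fgb, the fibrinogen beta chain, fell by 3.14 ± 0.20. Ppp1r3b, which directs a phosphatase to glycogen, fell by 2.90 ± 0.41. Upk3a, a uroplakin, fell by 2.70 ± 0.56 and Fam25c fell by 2.61 ± 0.26. The fructose transporter gene Slc2a5 fell by 2.15 ± 0.48. Acot11, a thioesterase, fell by 2.12 ± 0.41. Hk2, which commits glucose to glycolysis, fell by 2.10 ± 0.31. Poln, a DNA polymerase, fell by 2.09 ± 0.19 and Mtarc1, a mitochondrial reductase, fell by 2.07 ± 0.53. Mfsd4b1, Pianp and Tlcd3b fell by 2.04 ± 0.16, 2.02 ± 0.21 and 2.01 ± 0.51.

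Of these 30 genes, 21 kept their call when any 1 array was left out. Csn2 lost it without wild-type 1, wild-type 3, knockout 1 or knockout 3 (adjusted p = 0.0628, 0.0791, 0.0529 and 0.0770). Csn1s2a lost it without wild-type 1 or 3 (0.0871 and 0.103) and without knockout 1, 2 or 3 (0.0672, 0.0584 and 0.101). Ido1 lost it without wild-type 1, 2 or 3 (0.127, 0.0505 and 0.127) and without knockout 1 or 3 (0.114 and 0.149). Ucp1 lost it without wild-type 1 (0.101) and without knockout 1, 2 or 3 (0.0834, 0.0843 and 0.136). Upk3a lost it without wild-type 1, wild-type 3 or knockout 3 (0.0631, 0.0639 and 0.0823). Slc2a5 did so without wild-type 2, wild-type 3 or knockout 3 (0.0641, 0.0638 and 0.0608), and Acot11 without wild-type 2 or knockout 3 (0.0566 and 0.0647). Mtarc1 lost it without wild-type 2, wild-type 3, knockout 2 or knockout 3 (0.102, 0.112, 0.0699 and 0.0984). Tlcd3b lost it without wild-type 3, knockout 2 or knockout 3 (0.0833, 0.0848 and 0.125). With a variance prior that follows intensity and is robust to outliers, 12 of the 30 lost the call, at adjusted p between 0.0521 and 0.154: Olah, Sftpd, Chrdl2, Pigr, Csn2, Csn1s2a, Ido1, Ucp1, Upk3a, Slc2a5, Mtarc1 and Tlcd3b. Tlcd3b rests on a probe set that can match several transcripts, with 0 of its 3 other probe sets past the limma threshold. Without such probe sets, with averaged probe sets (difference −1.45) and with array weights it lost the call (0.0564, 0.0587 and 0.0528). Ucp1 and Mtarc1 lost it with averaged probe sets (0.0506 and 0.0557) and Mtarc1 with array weights (0.0564). Ido1, Slc2a5, Mtarc1 and Tlcd3b lost it with the skeletal muscle list mean as a covariate (0.0926, 0.0881, 0.113 and 0.124), a setting chosen after seeing the data. Their log2 differences were then −3.83, −1.90, −1.98 and −1.76.

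**Figure D1:**
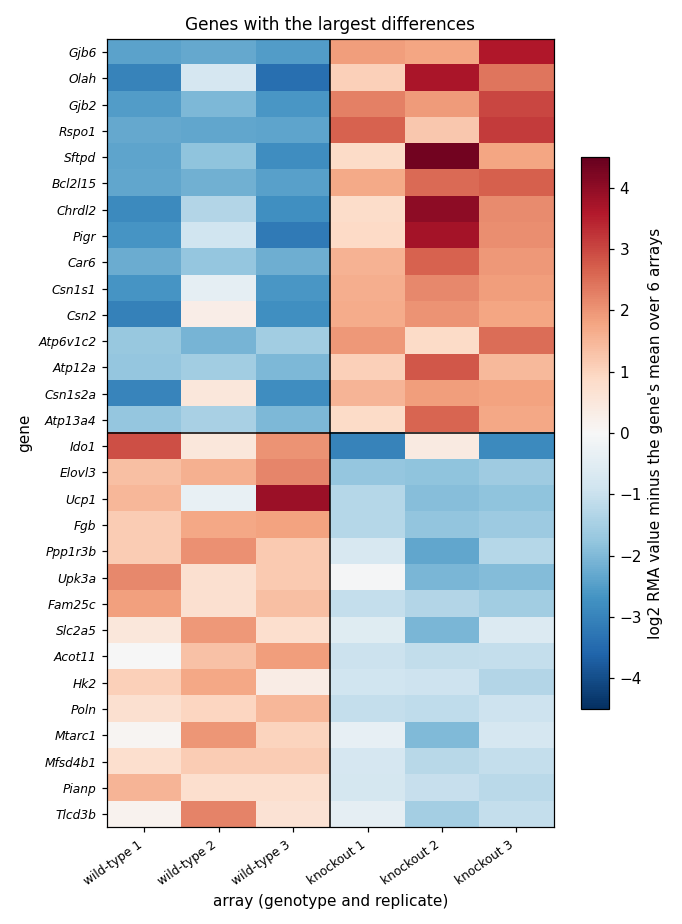
Heat map of the 30 genes named by size of change, with 1 row per gene, 1 column per array and colour for the log2 value minus the mean of that gene over the 6 arrays. Knockout columns are redder than wild-type columns for the 15 genes at the top (mean differences of 3.49 to 4.84) and bluer for the 15 at the bottom (−3.63 to −2.01), and wild-type 2 stands above the other wild-type arrays for the caseins.

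Of 22 measured genes of milk and secretory differentiation 8 were higher and 0 lower (9 higher and 1 lower when adjusted over the list alone), with a median log2 difference of 1.92 and a list mean of 9.23 ± 0.60 (SD, n = 3) in wild type against 10.99 ± 1.07 in knockout. Muc15, a mucin of the milk fat globule membrane, rose by 2.71 ± 0.23, Wfdc18, a whey acidic protein relative, by 3.22 ± 0.30, and Csn1s1 by 3.79 ± 0.54. Muc1, another milk fat globule mucin, rose by 2.02 ± 0.38 (adjusted p = 0.0150, and 0.0554 without wild-type 3). Wap, a major whey protein singled out here for its spread, was 6.95 ± 2.21 in wild type and 10.37 ± 2.03 in knockout (adjusted p = 0.118, and 0.0425 without wild-type 2). In wild-type 2 the log2 values of Csn2 and Wap were 11.71 and 9.50, against 8.36 and 5.56 in wild-type 1 and 8.65 and 5.79 in wild-type 3. The list was called higher by camera (adjusted p = 4.72e-06). That call was lost with an estimated correlation (adjusted p = 0.458) and by fry (adjusted p = 0.0959). Without wild-type 1, wild-type 3 or knockout 3, 4, 3 and 4 members were higher. Knockout 2 had the highest list mean, 12.18 against 10.14 and 10.64 in knockout 1 and 3, and without it the median was 0.78, with 9 members higher and 2 lower. The luminal epithelium list rose beside it, by a mean of 0.79.

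Of 21 measured members of the list of prolactin and STAT5 signalling in alveolar development 6 were higher and 0 lower (11 higher when adjusted over the list alone), with a median of 0.63. Besides Gjb2 and Gjb6, Elf5, a transcription factor needed for alveoli, rose by 2.31 ± 0.27, 4.95-fold, and Nfib, a transcription factor acting on milk genes, by 0.76 ± 0.10. The list mean was 7.58 ± 0.01 (SD, n = 3) in wild type and 8.6 ± 0.11 in knockout. The call (adjusted p = 1.09e-05) was lost with an estimated correlation (adjusted p = 0.241) and kept by fry (adjusted p = 0.00167).

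**Figure D2:**
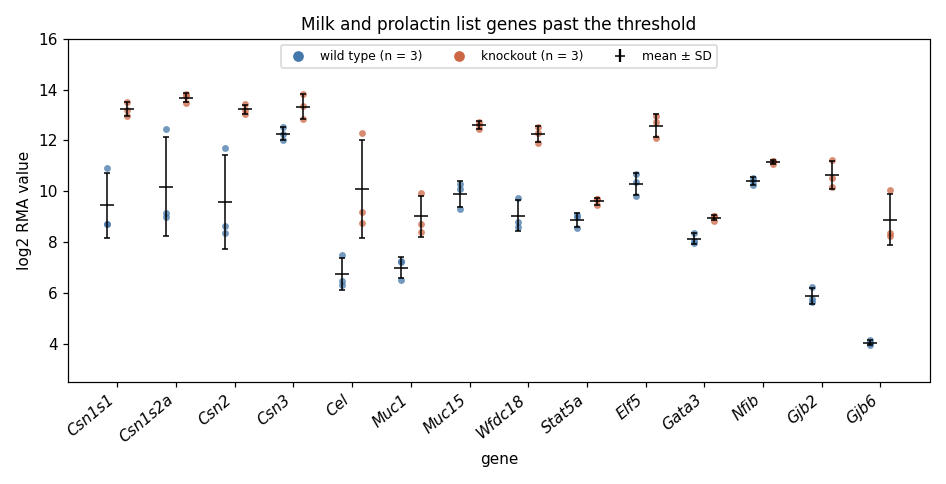
Log2 values of the members of the milk and prolactin lists that passed the threshold, with 1 point per array, wild type and knockout in separate colours, and black marks for the mean and SD of 3 arrays. The 3 knockout arrays lie above the 3 wild-type arrays for each gene shown, and 1 wild-type array sits above the other wild-type arrays for Csn2 (11.71).

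Lists of both epithelial layers had higher medians. Of 24 luminal genes 14 were higher and 2 lower (16 higher and 2 lower when adjusted over the list alone), with a median of 0.87. Spint2, a protease inhibitor, rose by 1.49 ± 0.09, the tight junction gene Cldn7 by 1.86 ± 0.14, the surface antigen Epcam by 1.55 ± 0.13 and Cldn8 by 3.06 ± 0.28. The 2 luminal genes that went the other way, named for that reason, were Prom1, which fell by 1.58 ± 0.26, and Foxa1, a partner of the oestrogen receptor, which fell by 1.31 ± 0.31. Foxa1 lost its call without wild-type 1, wild-type 3 or knockout 3 (adjusted p = 0.0915, 0.0955 and 0.0727), which left 1 luminal gene lower. Of 15 basal and myoepithelial genes 9 were higher and 0 lower (10 higher and 1 lower when adjusted over the list alone), with a median of 0.64. The basal keratin genes Krt5 and Krt14 rose by 1.25 ± 0.10 and 1.32 ± 0.19, smooth muscle actin Acta2 by 0.75 ± 0.10 and the basal transcription factor Trp63 by 1.39 ± 0.24. Without wild-type 1 or 3, 5 and 4 basal genes were higher. Camera called both lists higher (adjusted p = 8.06e-07 for luminal and 4.40e-06 for basal). Neither call held with an estimated correlation (adjusted p = 0.432 and 0.276).

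Cell division genes were higher in knockout in all 25 measured members by sign, 6 of them past the threshold (25 when adjusted over the list alone), with a median of 1.29. Mcm6, Mcm7 and Mcm5, parts of the replicative helicase, rose by 1.59 ± 0.36, 0.95 ± 0.22 and 1.29 ± 0.32, and the division marker Mki67 by 1.76 ± 0.45. Without wild-type 2 or 3 these 4 genes gave adjusted p between 0.0732 and 0.121. The list mean was 8.41, 7.70 and 9.26 in knockout 1 to 3, against 7.55, 6.79 and 7.29 in wild-type 1 to 3. The number of members past the threshold was 2, 0 and 0 without wild-type 1, 2 or 3, and 3, 21 and 1 without knockout 1, 2 or 3, and the median was 0.84 without knockout 3. The number was 0 with the muscle covariate, where the median was 1.25. Without the covariate and with all arrays, 25 members were higher at an unadjusted p under 0.05. The camera call (adjusted p = 3.78e-08) was lost with an estimated correlation (adjusted p = 0.458) and by fry (adjusted p = 0.111).

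Immediate early genes, which tissue handling also induces, were higher in 9 of 25 members and lower in 0 (10 higher and 1 lower when adjusted over the list alone), with a median of 0.36. Atf3, a stress-induced transcription factor, rose by 1.34 ± 0.18, Myc by 1.51 ± 0.20 and Ccn1, a secreted matrix protein, by 1.25 ± 0.22. Counts of higher members were 4, 4, 3 and 4 without wild-type 1, 2 or 3 or knockout 1, and 3 with the muscle covariate, and the median was 0.55 without knockout 3. Without knockout 2, 8 were higher and 3 lower. The call (adjusted p = 0.000546) was lost with an estimated correlation (adjusted p = 0.458) and by fry (adjusted p = 0.0745). Genes of protein folding and secretion in the endoplasmic reticulum were higher in 6 of 21 members and lower in 0 (8 higher and 1 lower when adjusted over the list alone), with a median of 0.34. The secretory transcription factor Xbp1 rose by 0.73 ± 0.10 and the disulphide isomerase Pdia3 by 0.63 ± 0.09 (adjusted p = 0.115 where all probe sets of the gene were averaged). Without wild-type 1, wild-type 3 or knockout 3, 3 members were higher each time. The median was 0.54 without knockout 1 and 0.11 without knockout 2, where 2 members were lower. This call (adjusted p = 0.00128) was lost with an estimated correlation (adjusted p = 0.604), by fry (0.154) and without knockout 2 (0.0740).

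Both lipid synthesis lists had lower medians, beside a white adipocyte list whose mean fell by 0.61 and a luminal list whose mean rose by 0.79. Of 23 fatty acid and triglyceride synthesis genes 16 were lower and 1 higher (17 lower and 2 higher when adjusted over the list alone), with a median of −0.79. The exception was Fads2, a desaturase of polyunsaturated fatty acids, which rose by 1.59 ± 0.10, 3.02-fold. Gpd1, which supplies the glycerol backbone, fell by 1.25 ± 0.15 and Mlxipl, a glucose-responsive transcription factor, by 1.6 ± 0.20. Dgat1, which completes triglycerides, fell by 0.73 ± 0.08. Its probe set can match several transcripts, and without such probe sets its difference was −0.02 (adjusted p = 0.939). Counts of lower members were 8, 10 and 9 without wild-type 2, wild-type 3 or knockout 3, and 8 with the muscle covariate. Of 18 cholesterol synthesis genes 8 were lower and 0 higher (11 lower when adjusted over the list alone), with a median of −0.51. Msmo1 fell by 1.02 ± 0.11, Fdft1, the squalene synthase, by 1.12 ± 0.12 and Nsdhl by 0.99 ± 0.16. Camera called both lists lower (adjusted p = 8.06e-07 and 0.00011). With an estimated correlation neither passed (adjusted p = 0.432 for each).

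Lists of fuel use had lower medians as well, beside falls of 0.61 and 1.20 in the means of the white and brown adipocyte lists. Of 20 genes of fatty acid oxidation and thermogenesis 8 were lower and 0 higher (13 lower when adjusted over the list alone), with a median of −0.75. Besides Elovl3, Ppargc1a, a coactivator of mitochondrial genes, fell by 1.71 ± 0.17, the fatty acid transporter gene Slc27a1 by 0.94 ± 0.10 and Cox8b, a cytochrome oxidase subunit of brown fat and muscle, by 1.06 ± 0.15. Without wild-type 3, 2 members were higher and 8 lower. There were 5 lower members without knockout 3 and 14 with the muscle covariate. The call (adjusted p = 2.84e-06) was lost with an estimated correlation (adjusted p = 0.458) and by fry (adjusted p = 0.0507). All 25 oxidative phosphorylation genes were below wild type by sign, 11 of them past the threshold (16 when adjusted over the list alone), with a median of −0.49. Sdhb fell by 0.58 ± 0.10, Uqcrfs1 by 0.55 ± 0.09 and Ndufs1 by 0.70 ± 0.12. The count was 6, 3 and 5 without wild-type 2, wild-type 3 or knockout 3. This call (adjusted p = 3.78e-08) gave adjusted p = 0.458 with an estimated correlation. Of 19 glycolysis genes 7 were lower and 1 higher (8 lower and 2 higher when adjusted over the list alone), with a median of −0.49. The isozyme gene Aldoc rose by 1.98 ± 0.20, while the insulin-responsive glucose transporter gene Slc2a4 fell by 1.5 ± 0.18 and Hk2 by 2.10 ± 0.31. Lower members numbered 3, 4 and 2 without wild-type 2, wild-type 3 or knockout 3, and 4 with the muscle covariate. The glycolysis call (adjusted p = 0.00187) gave adjusted p = 0.454 with an estimated correlation.

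Both adipocyte lists had lower medians. Of 20 white adipocyte genes 12 were lower and 0 higher (15 lower when adjusted over the list alone), with a median of −0.67 and a list mean of 11.22 ± 0.28 (SD, n = 3) in wild type against 10.60 ± 0.20. Pparg, the master regulator of fat cells, fell by 1.11 ± 0.13, the hormone gene Retn by 0.78 ± 0.10 and Thrsp, a lipogenic protein, by 0.66 ± 0.10. Without knockout 3 there were 5 lower members, and without wild-type 3, 1 was higher. Of 13 brown adipocyte genes 5 were lower and 0 higher (9 lower when adjusted over the list alone), with a median of −1.12: Elovl3, Ppargc1a, Cox8b, Ucp1 and Pank1, which makes coenzyme A and fell by 1.35 ± 0.17. The muscle covariate gave 8. The brown list shares 7 genes with the oxidation and thermogenesis list, and its mean in wild-type 1 to 3 was 7.75, 7.41 and 8.76. Camera called the white and brown lists lower (adjusted p = 2.42e-07 and 6.84e-05), which gave adjusted p = 0.432 and 0.458 with an estimated correlation.

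Lymphocyte, neutrophil and mast cell lists had lower medians. Of 17 B and plasma cell genes 15 were lower and 0 higher (15 lower when adjusted over the list alone), with a median of −0.70. The B cell surface genes Ms4a1, Fcmr, Fcer2a and Cd22 fell by 0.88 ± 0.11, 0.86 ± 0.11, 1.0 ± 0.13 and 0.91 ± 0.12. Lower B cell members numbered 8, 9 and 8 without wild-type 1, 2 or 3, and 5 without knockout 3. Of 18 T and natural killer cell genes 9 were lower and 0 higher (14 lower when adjusted over the list alone), with a median of −0.50. The costimulatory receptor gene Cd28 fell by 0.76 ± 0.14 and Cd5 by 0.77 ± 0.14 (adjusted p = 0.0149, and 0.0513 without knockout 3). Lower T cell members numbered 5 and 3 without wild-type 2 or 3, and 4, 5 and 1 without knockout 1, 2 or 3. Of 16 neutrophil and mast cell genes 9 were lower and 0 higher (13 lower and 1 higher when adjusted over the list alone), with a median of −0.61. S100a9, a calcium-binding protein of neutrophils, fell by 1.69 ± 0.17, and the mast cell genes Cpa3 and Ms4a2 by 0.87 ± 0.11 and 0.64 ± 0.11. Here 4, 4 and 5 members were lower without wild-type 1, 2 or 3, and 4 without knockout 3 or with the muscle covariate, and 1 was higher without knockout 2. The 3 lists were called lower by camera (adjusted p = 3.78e-08 for B, 9.88e-06 for T and 1.97e-05 for neutrophil and mast cells). With an estimated correlation they gave adjusted p = 0.432, 0.458 and 0.245, and fry gave 0.0535 for the T cell list.

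Interferon response genes were lower in 2 of 21 members and higher in 0 (2 lower when adjusted over the list alone), with a median of −0.40. Ifi27 fell by 0.67 ± 0.13 (adjusted p = 0.0169, and 0.0584 and 0.0622 without wild-type 3 or knockout 3). Usp18, which removes the modifier ISG15, fell by 0.96 ± 0.24 (adjusted p = 0.0376, and 0.0592, 0.0806, 0.0987 and 0.127 without wild-type 1, wild-type 3, knockout 1 or knockout 3). The numbers lower were 1 and 0 without wild-type 1 or 3, and 1, 4 and 0 without knockout 1, 2 or 3, and the median was −0.18 without wild-type 1. The list's call (adjusted p = 0.0331) was lost with an estimated correlation (adjusted p = 0.699), by fry (0.410), among probe sets above the median intensity (0.0502), and without wild-type 1 (0.290), knockout 1 (0.199) or knockout 3 (0.0664).

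Of 11 measured caveola genes 1 was lower and 0 higher (1 lower when adjusted over the list alone), with a median of −0.36. This stood beside medians of −0.67 for the white adipocyte list and −0.15 for the endothelium list. The list was called lower by camera (adjusted p = 0.00461), a call lost with an estimated correlation (adjusted p = 0.432). Nos3, the endothelial nitric oxide synthase held in caveolae, fell by 0.70 ± 0.11. The coat genes Cavin1, Cav2 and, added here as the best known caveola gene, Cav1 differed by −0.36 ± 0.12, −0.34 ± 0.11 and −0.39 ± 0.15 (adjusted p = 0.0868, 0.0926 and 0.131). Cavin1 reached adjusted p = 0.0426 without knockout 2, where 3 members were lower.

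Skeletal muscle genes, a marker of neighbouring tissue, had a median of −1.29, with 0 of 28 members past the limma threshold (0 when adjusted over the list alone, 2 lower at an unadjusted p under 0.05). The median was −0.33 without wild-type 2, −2.09 without wild-type 3 and −0.65 without knockout 1. Myl1, a myosin light chain, differed by −1.57 ± 0.44 (adjusted p = 0.0563, and 0.0393 without wild-type 3, where 6 members were lower). The spread between arrays of one genotype was wide, at 6.86 ± 1.39 (SD, n = 3) in wild type against 5.83 ± 0.74 in knockout. The call (adjusted p = 0.00965) was lost with an estimated correlation (adjusted p = 0.609), by fry (0.360), and without wild-type 1 (0.0524), wild-type 2 (0.145) or knockout 1 (0.0830).

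Of 22 endothelial genes 4 were lower and 1 higher (5 lower and 2 higher when adjusted over the list alone), with a median of −0.15. The junction gene Cldn5 rose by 0.97 ± 0.18. The lower genes, named because they are few, were the lymphatic receptor gene Lyve1 (−0.96 ± 0.20) and Kdr, Ramp2 and Tek (−0.49 ± 0.11, −0.46 ± 0.10 and −0.45 ± 0.10). These 4 gave adjusted p between 0.0524 and 0.0774 without wild-type 2, and between 0.0659 and 0.0861 without knockout 3. Lower endothelial members numbered 1, 0 and 1 without wild-type 1, 2 or 3, 2 and 0 without knockout 1 or 3, and 1 with the muscle covariate, and without knockout 2 the median was −0.04, with 2 members higher. The list's call (adjusted p = 0.0498) was lost with an estimated correlation (adjusted p = 0.488), by fry (0.104), with averaged probe sets (0.122), among probe sets above the median intensity (0.0526), with the muscle covariate (0.0669), and without wild-type 2 (0.139), wild-type 3 (0.0920) or knockout 2 (0.186). Of 21 fibroblast genes 7 were lower and 0 higher (10 lower and 1 higher when adjusted over the list alone), with a median of −0.26. Igfbp6, which binds insulin-like growth factors, fell by 0.67 ± 0.13 (adjusted p = 0.0152, and 0.0538, 0.0581 and 0.0614 without wild-type 1, wild-type 3 or knockout 3). Lower fibroblast members numbered 1, 2 and 0 without wild-type 1, 2 or 3, and 4 and 0 without knockout 2 or 3, and the median was −0.41 without knockout 1. Without knockout 2, 1 was higher. The fibroblast call (adjusted p = 0.0285) was lost with an estimated correlation (adjusted p = 0.609), by fry (0.307) and without wild-type 1 (0.126) or knockout 2 (0.240).

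Of 34 lists fixed beforehand, camera called 7 higher and 15 lower. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way rather than more than other genes do, called 3 higher and 10 lower.

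**Figure D3:**
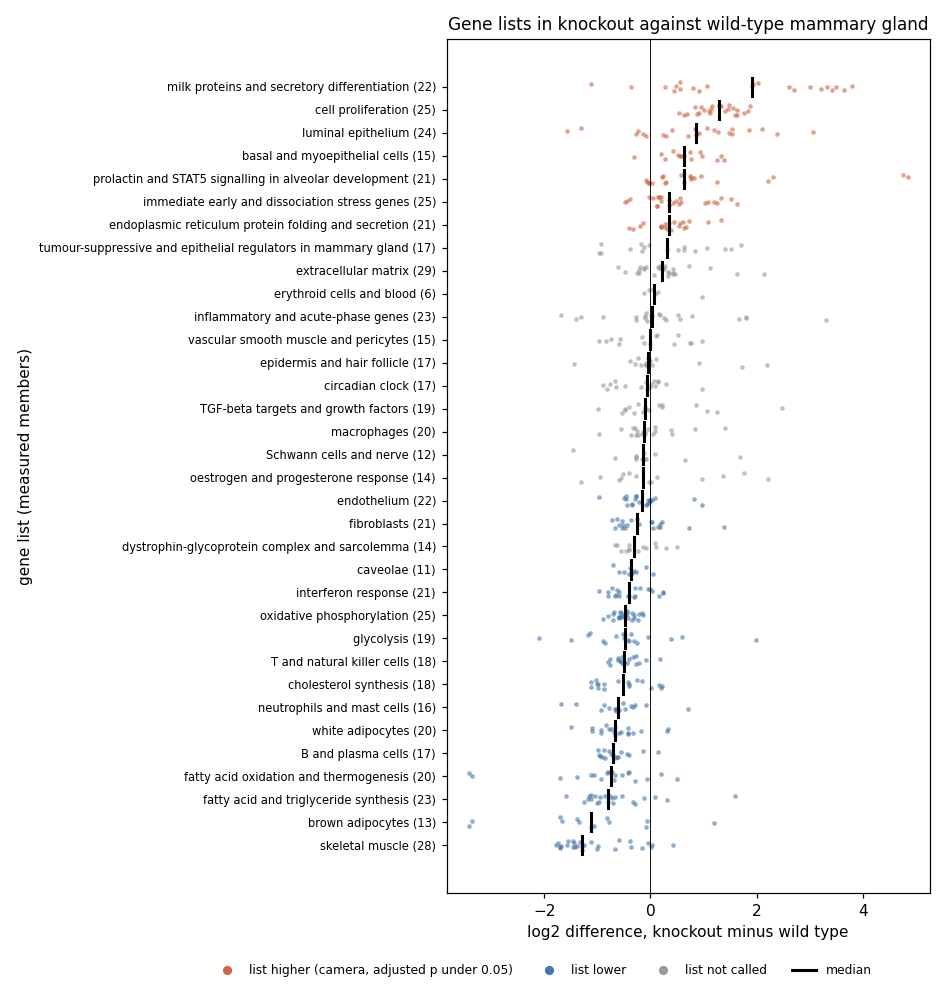
Log2 difference between knockout and wild type for each measured member of the 34 lists, with 1 point per gene, a black bar at the list median and colour for the camera call at the preset correlation. Medians run from −1.29 for skeletal muscle to 1.92 for milk proteins, and the members of many lists lie on both sides of 0.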

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

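The 18S ribosomal RNA control probe sets, which the comparisons leave out, read higher on knockout 1 than on any wild-type array. The 3′, middle and 5′ sets had log2 values of 8.62, 8.46 and 6.66 there, against at most 6.63, 6.01 and 4.67 in wild type. On knockout 2 and 3 the 3′ set read 6.40 and 6.21, so the signal was not shared by the genotype. The log2 excess of 3′ over 5′ actin signal on knockout 1 was 2.55, against 2.63 to 2.86 in wild type and 3.16 and 2.61 on knockout 2 and 3, and that of Gapdh was 3.74, against 3.65 to 4.12 in wild type and 3.20 and 3.72 on knockout 2 and 3. Knockout 2 thus had the highest actin and the lowest Gapdh excess of the 6 arrays, and it also had the highest milk list mean (12.18). Without it the milk list median was 0.78 rather than 1.92. Leaving out knockout 1 gave 2485 genes past the threshold, of which 2161 were among the 2941 called with all arrays.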

How the results depend on the processing

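The muscle covariate was chosen after seeing the data. Over all probe sets, 5547 passed. The count was 8724 at an adjusted p under 0.10 and 3377 with at least 1.5-fold change required, as a looser or stricter rule must give, and stayed within 1.5 times under the other scalings, priors, weights, filters and the covariate (3941 to 6645). Leaving out 1 array, which leaves fewer samples, gave 2218 to 5987 probe sets and 1235 to 3181 genes. For genes the other settings gave 2102 to 3486. The share of calls that were higher, 46.6%, ran from 45.8% to 49.2% across scalings. Of 34 lists, 22 were called, 0 by camera with an estimated correlation and 13 by fry, 12 of them shared, and 20 to 21 with 1 array left out. For the prolactin list the estimated correlation was −0.0075, below the preset 0.01, so a higher correlation between its genes cannot be why its call ended. With an estimated correlation camera also tests on the 4 residual degrees of freedom, and with a preset one on far more. Every list thus loses power at once, so a lost call does not by itself show that correlation between genes undid it. How much each of these took from the other calls was not tested. For the milk list adjusted p was 0.458 with an estimated correlation and 0.0959 by fry, and ran from 1.47e-08 to 0.000276 with 1 array left out. For the prolactin list it was 0.241 with an estimated correlation and 1.40e-06 to 3.20e-05. Among probe sets above the median intensity 32 lists kept enough members, and Cav3 had no value.

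Directions turned only for values far from their thresholds, and the cause was not tested. Cav3 ran from −0.14 to 0.0063 with 1 array left out, the latter without wild-type 2. Bpgm was −0.0132 with the muscle covariate, which gave adjusted p = 0.989 for the erythroid and skeletal muscle lists, the latter by construction. By fry the TGF-beta list gave 0.752 and the epidermis list 0.972, among probe sets above the median intensity the TGF-beta list gave 0.626 and the vascular smooth muscle list 0.978, all with the direction turned. With 1 array left out, the direction turned for the TGF-beta list (0.870 without wild-type 2, 0.801 without knockout 3), the vascular smooth muscle list (0.761 and 0.998 without wild-type 1 or 3, 0.929 without knockout 3), the epidermis list (0.995 and 0.971 without knockout 2 or 3) and the inflammatory list (0.688 without knockout 2). Over all 6 such fits the adjusted p ran from 0.695 to 0.979 for the TGF-beta list, 0.774 to 0.995 for the epidermis list and 0.378 to 0.852 for the inflammatory list. For the 30 genes named by size, 26 of 297 values lost the call in the other settings and 33 of 180 with 1 array left out, and 0 turned. Dim signal limits genes whose values lie in the range of the Y-linked probe sets, 1.90 to 3.57.

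With the replicate number as a replicate block, 5352 probe sets, 2870 genes and 21 lists passed. The endothelium and fibroblast lists lost their call (adjusted p = 0.0502 and 0.0540) and the extracellular matrix list gained one (0.0182). Of the 30 genes named by size, Ido1, Slc2a5, Mtarc1 and Tlcd3b lost theirs (0.0693, 0.0513, 0.0706 and 0.0602). Deviations of same-numbered arrays from their group means correlated at −0.05, 0.19 and −0.02. On principal component 2, wild-type 2 and knockout 2 had values of −13.7 and −22.6, while all other arrays had positive values. With so few arrays per genotype, these values cannot decide whether the numbers pair the samples. The block turned the direction of the uncalled TGF-beta and vascular smooth muscle lists (adjusted p = 0.967 for each).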

Other observations

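Tests of the epithelial share, of dilution and of the window around Cav3, and the muscle covariate, were chosen only after the results were seen. Hormone and growth factor genes moved in both directions. Of 14 oestrogen and progesterone response genes 2 were higher and 4 lower (3 higher and 4 lower when adjusted over the list alone), and the list was not called (adjusted p = 0.663, median −0.15, mean 0.13). Id4, an inhibitor of transcription factors, rose by 1.77 ± 0.21 (SE, log2) and Wnt4, a progesterone target, by 0.98 ± 0.24. The oestrogen receptor gene Esr1 fell by 0.55 ± 0.10, Cxcl12 by 0.52 ± 0.10, Foxa1 by 1.31 ± 0.31 and Fst by 0.94 ± 0.24. Of these only Id4 kept its call whichever array was left out. Without knockout 3, 1 member was higher and 0 lower, with adjusted p = 0.0513 for Esr1, 0.0727 for Cxcl12 and Foxa1, 0.116 for Wnt4 and 0.137 for Fst. Without wild-type 1, 2 or 3, 0, 2 and 2 were lower. Higher members numbered 1 without wild-type 2, wild-type 3 or knockout 1 and 4 without knockout 2, and the median was −0.36 without knockout 1. Of 19 TGF-beta targets and growth factors 3 were higher and 4 lower (3 higher and 5 lower when adjusted over the list alone), with no call for the list (adjusted p = 0.915, median −0.09, mean 0.12). Tgfb2 rose by 2.48 ± 0.18, 5.56-fold, Tgfb3 by 1.07 ± 0.16 and Ccn1 by 1.25 ± 0.22. The lower ones were Fgf10, Tgfbr2, Tgfbi and Inhbb, at −0.48 ± 0.11, −0.49 ± 0.12, −0.41 ± 0.10 and −0.98 ± 0.26. The 3 higher genes passed whichever array was left out, while 1, 0 and 2 lower ones did without wild-type 1, 2 or 3, and 1 and 0 without knockout 1 or 3.

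Among 29 extracellular matrix genes 2 were higher and 0 lower (1 higher when adjusted over the list alone; list adjusted p = 0.120, and 0.0140 and 0.00501 without wild-type 1 or knockout 2): Thbs1 by 2.14 ± 0.33 and Tnc by 1.64 ± 0.42, the latter at 0.0897 to 0.119 without wild-type 1, 2 or 3 or knockout 3. Higher matrix genes numbered 1 without wild-type 2, wild-type 3 or knockout 3 and 4 without knockout 2. Among 12 Schwann cell genes Sox10, also active in mammary progenitors, rose by 1.68 ± 0.12, and Pmp22 differed by −0.67 ± 0.18 (adjusted p = 0.0493, and 0.0857, 0.122 and 0.150 without wild-type 1, 2 or 3 and 0.0507 and 0.118 without knockout 2 or 3), with 1 higher and 2 lower when adjusted over the list alone (list 0.516). Among 17 epidermal genes the keratin gene Krt15 rose by 2.19 ± 0.32 and Calml3 by 1.72 ± 0.28, while Sbsn differed by 0.92 ± 0.25 (adjusted p = 0.0488, and 0.140 without wild-type 2). That made 3 higher and 0 lower (3 higher and 2 lower when adjusted over the list alone; list 0.915, median −0.05, mean 0.12). Among 17 tumour-suppressive and epithelial regulators 6 were higher and 3 lower (9 and 3 when adjusted over the list alone; list 0.136), with Myc, the adhesion gene Cdh1 (1.06 ± 0.15) and the cell cycle inhibitor Cdkn2c (−0.92 ± 0.14) leading. There were 3 higher without wild-type 3, 1 lower without wild-type 1 or 2, and 2 higher and 1 lower without knockout 3. Of 15 vascular smooth muscle genes 4 were higher, each also a basal marker (Acta2, Cnn1, Myh11 and Tagln), and 4 lower, led by Cspg4 and Des at −0.98 ± 0.15 and −0.74 ± 0.13 (5 and 5 when adjusted over the list alone; list 0.997, median −0.02, tested direction up). Higher ones numbered 2, 2 and 1 without wild-type 1, 2 or 3 and 2 without knockout 3. Of 14 dystrophin complex genes 3 were lower, with Sgcb at −0.64 ± 0.09 leading (1 higher and 5 lower when adjusted over the list alone; list 0.0682, and 0.0402 by fry, 0.0194 with averaged probe sets and 0.0311 without wild-type 1). Without wild-type 2 or knockout 3, 1 was lower. Of 23 inflammatory genes 2 were higher and 2 lower (3 and 3 when adjusted over the list alone; list 0.711): Lbp (1.80 ± 0.36), Cxcl2 (0.52 ± 0.12), S100a9 (−1.69 ± 0.17) and Hp (−0.89 ± 0.18), of which S100a9 alone passed whichever array was left out. Inflammatory genes numbered 0 higher without wild-type 1, 2 or 3, 1 higher and 4 lower without knockout 2, and 1 higher and 1 lower without knockout 3. Of 20 macrophage genes 3 were higher and 2 lower (3 and 2 when adjusted over the list alone; list 0.409), and 0 passed without wild-type 1 or knockout 3, 1 higher and 0 lower without wild-type 2, and 0 higher and 2 lower without wild-type 3. Of 17 clock genes 1 was higher and 2 lower (1 and 2 when adjusted over the list alone; list 0.316): Npas2 (0.97 ± 0.21), Cry2 (−0.76 ± 0.15) and Tef (−0.65 ± 0.17), while 1 was higher and 0 lower without wild-type 3 or knockout 3, and 0 higher and 1 lower without knockout 1. Of 6 erythroid genes 0 passed in limma (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05; list 0.669).

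The real split of the 6 arrays gave 5547 probe sets, while the highest of the other splits gave 0 in limma (at most 2020 at an unadjusted p under 0.05, against 12464). Of 10 splits, 1 gave as many, the real one, and 10 splits are too few for a share under 0.05.

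The rise of milk and prolactin list genes was set against a larger epithelial share of the tissue and against the RNA quality of knockout 1. After each array's luminal list mean, 0.79 higher in knockout, was subtracted, 9 of the 14 called members stayed higher (p adjusted over the 43 measured members). The same subtraction, with each luminal gene set against the mean of the others, left 9 of the 14 called luminal genes higher, so this count does not separate milk genes from epithelial markers. Among all 24 luminal genes 9 were higher and 7 lower after it, so the luminal genes did not rise alike. Of the 14 called members 7 rose by more than the highest luminal gene (3.06), but these are the top genes of the pattern and do not settle it for the lists. Over all 43 members, 22 lay above the luminal change and 21 below it by sign, 9 and 7 of them past the threshold. Their mean rose by 0.61 ± 0.45 (SE, log2) more than the luminal mean, with 0.97 ± 0.80 for the milk list and 0.23 ± 0.15 for the prolactin list. For the lists as sets, a larger epithelial share may therefore underlie the rise. With 3 arrays per genotype it cannot be told apart from a change within the epithelium. Without knockout 1, 12 of the 14 stayed higher. Csn2 and Csn1s2a lost the call with fewer arrays (adjusted p = 0.0529 and 0.0672), while their log2 differences were 3.74 and 3.61, against 3.65 and 3.50 with all arrays, which argues against the RNA quality of knockout 1 as the cause. Knockout 1 had the lowest milk list mean of the knockout arrays (10.14), so leaving it out could not lower the mean difference of that list. The test does not cover knockout 2, whose actin and Gapdh values were the most extreme. Without knockout 2 the milk list median was 0.78 rather than 1.92, with 9 members higher and 2 lower. The genotype, the RNA quality of knockout 2 and the untested stage of the oestrous cycle stay open.

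The fall of lymphocyte lists was set against dilution by epithelium and against less lymph node tissue. The B cell list fell by 0.57 ± 0.12 (SE, log2) more than the macrophage and endothelium lists (difference −0.57), and the T cell list by 0.37 ± 0.14 more. Dilution lowers all other cell types alike, but the margin depends on the reference lists, which were chosen after the results were seen. List means fell by 0.65 for B cells, 0.61 for white adipocytes and 0.60 for neutrophils and mast cells. They fell by 0.15 for fibroblasts, 0.08 for Schwann cells and 0.02 for vascular smooth muscle. Whether dilution is the whole cause is therefore not decided, and the margin was smaller for T cells. Genes of lymph node stroma, a list of 9 with 6 measured and 0 in the other lists, had a median difference of −0.32, with 4 lower at an unadjusted p under 0.05, led by the follicle chemokine gene Cxcl13 (9.94 in wild type, 9.03 in knockout). Less lymph node in the knockout samples is therefore a candidate explanation, though the addressin gene Madcam1 of the same list went the other way, by 1.57 ± 0.23. A lower number of lymphocytes in the gland itself was not tested and stays open.

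Sequence of the donor strain around a targeted allele could bring differences near Cav3 that are not due to its loss. By gene order in assembly GRCm38.p6, 59 of 281 genes within 20 Mb of Cav3 were called (21.0%, against 16.2% elsewhere, odds ratio 1.38 with a confidence interval of 1.01 to 1.85, Fisher's exact p = 0.0338). Of 497 windows of as many genes elsewhere, 15 were as high. These windows overlapped, each sharing most of its genes with the next, so they are not independent and the 15 may come from few regions. On the whole chromosome the odds ratio was 1.28 (1.08 to 1.51, Fisher's exact p = 0.00342, 195 of 991 genes), the highest of 20 chromosomes. Both rules set beforehand were met there: a Fisher's exact p under 0.05 for the explanation, and an odds ratio below 1.5 against it. The explanation therefore cannot be told apart there from a chance excess, and the rest of the chromosome was also raised (19.2%). Genes are not independent replicates, and strain differences are a candidate explanation for the excess. The count cannot tell whether they also bear on the 2870 called genes with a position outside the window. Inside it, 26 were higher and 33 lower, the largest changes being Pianp (−2.02 ± 0.21), Zfp239 (1.77 ± 0.15) and Tuba8 (−1.73 ± 0.15). Of the list genes named earlier, Pparg (−1.11 ± 0.13), Usp18 (−0.96 ± 0.24) and Cxcl12 (−0.52 ± 0.10) also lie there.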
